A study of Mus musculus with 5 samples.

How the data were processed

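Expression was measured by two-colour hybridisation on 5 oligonucleotide arrays from RNA of 4 sorted mouse cell populations. Per the labels' protocols, total RNA was column-purified, amplified as amino allyl RNA and coupled to Cy3 or Cy5. The direction of each ratio, Cy5 over Cy3, came from the dyes in the labels. The scanner software, gene model and genome build behind the deposited files are not given in the sources used here.

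The deposited scanner intensity values are, per the file headers, a median signal and a background for each channel. Testing on the files showed that the background holds 1 value for each of 48 blocks of 625 spots, that the median signal already had it subtracted, and that the deposited intensity is this signal times 1 factor per channel. The deposited ratio is the quotient of these intensities and is 0 for spots marked Bad. The deposited series table holds log2 values of 28524 probes. Set against the scanner ratios, each column equalled the log2 ratio minus 1 constant, with a range of differences of 1.00e-06, so its scale and direction were settled. Column medians were -0.0846, -0.0599, -0.0578, -0.00732 and -0.0728 in the order Bra over Rex1, Flk1 over Rex1, Nkx2.5 over Rex1, Nkx2.5 over Bra and Nkx2.5 over Flk1. Its probes were Bad on at most 2 arrays, and 407, 531, 765, 30 and 96 Bad spots held values whose origin stays unknown.

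Foreground signals, rebuilt as median signal plus background, were background-corrected with normexp at an offset of 50 and normalised within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Tables were made in Python 3.11.15. Control, empty and quality check spots were left out, which left 28845 probes. Spots marked Bad were to be left out only where well above background in both channels, which held for 0 of them, so all were kept. A probe was well above background where its signal exceeded percentile 95 of 96 negative control spots of that array and channel. Probes were named through a RefSeq gene table of assembly GRCm38.p6, used for names alone, with 8056 matched by accession, 5226 by symbol and 5081 by a unique synonym. For 558 probes the name in the files was kept and 9924 stayed unnamed. The brightest probe stood for each gene, giving 14959 named genes and 9840 unnamed transcripts.

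Before the data were examined, the groups, the size rule, the rule for named genes, 29 gene lists and the other settings to be tried were fixed. No test between populations was made, because each pair was hybridised once. The first reading of a comparison was its array, and the second came from the other arrays of its triangle. For Nkx2.5 over Rex1 the second reading was the mean of the routes through Bra and Flk1, and dye bias does not cancel in it. A gene passed where both readings reached a log2 ratio of 1 in size with the brighter population well above background. A gene dim in a population on every array of it was given as a lower bound on the fold, from channels normalised by loess and Aquantile, which stays open to dye bias without dye exchange. Of the 41 bounds of named genes 31 lay above the smaller reading of the same gene, so a bound is given only where both readings reach it, and other dim genes are given by their readings where they passed. This restriction was set after the values were seen, and it does not turn a bound into a guaranteed minimum. A fold given below as at least a value is an estimate of that bound. List medians were placed among 10000 random lists of the same size drawn within 20 intensity bins, as a description of these arrays, and a list stood apart where both readings lay outside percentiles 2.5 to 97.5. The gap between routes around each triangle gave an average error of 1 array, with errors taken as equal and independent between arrays.

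Named genes were, per comparison, the 4 sort markers, the 6 highest and the 6 lowest passing genes well above background in both populations by the smaller of their readings, the 4 largest bounds in each direction, and leading and opposing members of the lists discussed. RIKEN and predicted names were passed over. A gene that the rule also took is not reported here. Pou5f1, Myh7 and Lrrc2, and Nanog in Bra over Rex1, lie outside this rule and were named after their values were seen. In Nkx2.5 over Bra the rule itself took Nanog. The lists covered sort markers, pluripotency, post-implantation epiblast, primitive streak, cardiac and lateral mesoderm, paraxial mesoderm, blood, endothelium, cardiac transcription factors, sarcomere, calcium handling, energy metabolism, smooth muscle, epicardium, endoderm, neural ectoderm, epithelial junctions, mesenchyme, fibroblast feeder, anterior and posterior Hox, Wnt, BMP and Nodal, Notch, cell cycle and its inhibitors, dissociation stress, primordial germ cell and housekeeping genes. Of 469 listed genes 449 were on the array.

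The rule was tested on simulated data in which 200 of 24799 genes changed in Nkx2.5 alone, with errors from each gene's own triangle gaps. The changed genes were drawn only from genes well above background in both channels of every array. In Nkx2.5 over Rex1 the rule called 28.5% of genes changed by a fold of 2, 97.5% at a fold of 3 and 99.5% at a fold of 4. In Nkx2.5 over Bra it called 19.0%, 96.0% and 100.0%. These rates do not cover genes dim in a population. Such genes, dim in Rex1, made up 391 of the 602 higher calls in Nkx2.5 over Rex1, and their recovery was not tested. The number of arrays limits the precision of every value. The other settings were median centring, no background subtraction, the scanner ratio, the deposited table, other filters on dim probes, each reading alone, a dye term, a limma loop fit with adjusted p under 0.05 that compares hybridisations rather than samples, a fold of 4 and the mean of all probes. Leaving out Bad spots and requiring a bound of 2-fold for dim genes were added after seeing the data.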

Results

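Mouse embryonic stem cells were differentiated as embryoid bodies, cell aggregates in which cardiac development can be followed in culture, and marker-positive cells were isolated at successive stages. RNA came from 4 populations: undifferentiated cells positive for Rex1 (gene Zfp42) at day 0, early mesoderm positive for Brachyury (Bra, gene T) at day 4.5, cardiac mesoderm positive for Flk1 (gene Kdr) at day 4.5, and cardiac progenitors positive for Nkx2.5 (gene Nkx2-5) at day 7.5. Pairs of populations were hybridised on 5 two-colour oligonucleotide arrays of 30000 spots each. Each pair was hybridised on 1 array, with no dye exchange and no replicate sample, so no value below has a spread between samples and no test between populations was possible. Rex1 RNA was in the Cy3 channel on each of its arrays and Nkx2.5 RNA in the Cy5 channel on each of its arrays.

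The arrays form closed triangles, so each comparison was read along separate routes. The first log2 ratio given for a gene is from the array that carried both populations, and the second is from the remaining arrays of the triangle. A gene counted as higher or lower only where both readings reached a log2 ratio of 1 in size, which is a fold of 2, and where the brighter population was well above background. Over 24164 genes and unnamed transcripts the triangles failed to close by an SD of 0.391 through Bra and 0.440 through Flk1. If errors were equal and independent between arrays, this gives an average error of 0.240 on the log2 scale for 1 array. The arrays were not alike. The SD of all log2 ratios was 0.237 on the array of Nkx2.5 and Bra and 0.325 on that of Nkx2.5 and Flk1. It was 0.427 to 0.481 on the arrays with Rex1. The gaps of the triangles, which share the array of Nkx2.5 with Rex1, correlated at r = 0.519 across genes. The average error covers hybridisation and dye only and does not describe each array. Without background subtraction the ratios shrank, and no comparison kept over 3 calls in either direction. Simulated unchanged genes with each gene's own error gave between 1 and 18 calls per direction and comparison. The simulated errors were independent between arrays and, for each gene, of equal size on all arrays. These counts therefore leave out calls from a bias that arrays share, such as one in the Rex1 channel.

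The signal differed between arrays. In Cy3 the median net signal was 0.314, 0.345 and 0.307 times the local background on the arrays with Rex1, against 0.993 on the array of Nkx2.5 and Bra and 0.613 on that of Nkx2.5 and Flk1. The share of probes well above background in Cy3 was correspondingly 77.6%, 84.4% and 81.0% against 90.2% and 91.5%.

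**Figure D1:**
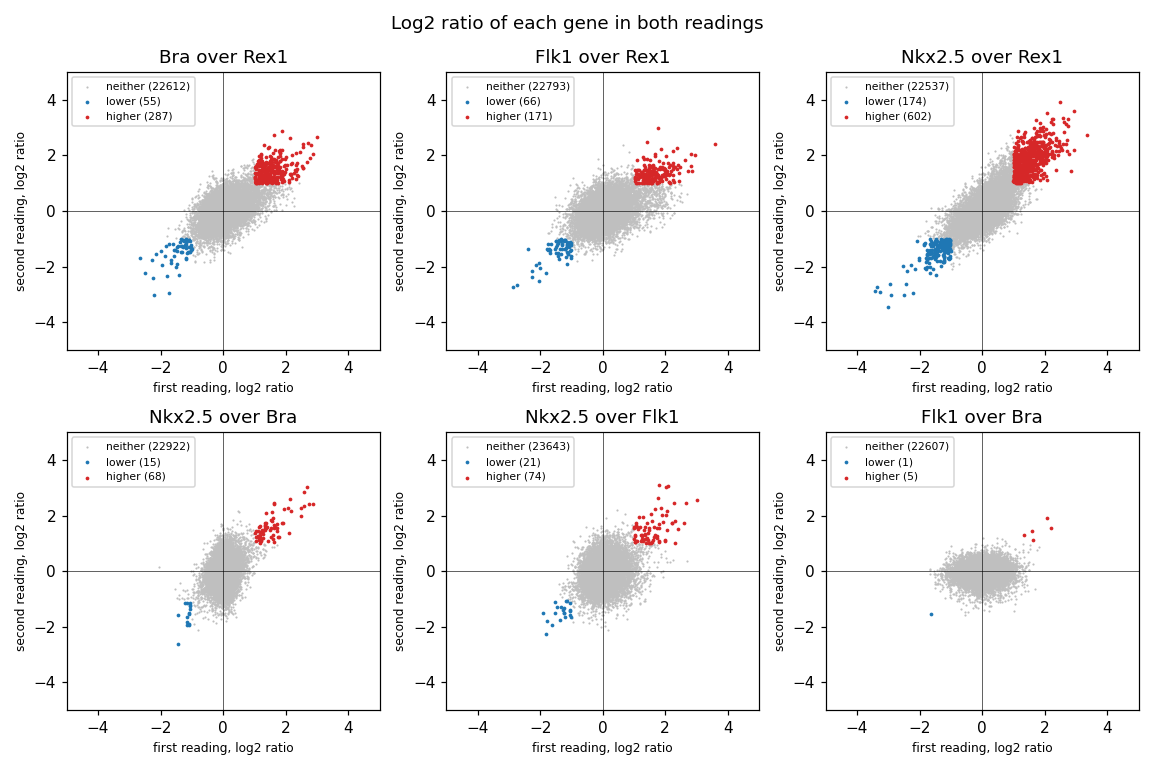
Each point is 1 gene or unnamed transcript, with the log2 ratio of the first reading on the x axis and of the second reading on the y axis, for the 6 comparisons; red and blue points passed the size rule in both readings and grey points did not. Nkx2.5 over Rex1 has 602 red and 174 blue points, and Flk1 over Bra has 5 and 1.

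The comparison of Bra with Rex1 asked which genes differed between early mesoderm and undifferentiated cells. Of 27 genes of undifferentiated stem cells 5 were lower in the Bra population, and 3 of 26 primitive streak genes were higher. Zfp42, the sort marker of the Rex1 population and also counted among those 5 stem cell genes, was lower with log2 ratios of -1.74 and -1.19. Fgf8, a growth factor gene of the primitive streak, was higher at 2.36 and 1.72, with Rex1 well above background on 1 of 3 arrays. T, the Brachyury gene itself, had ratios of 1.07 and 0.73 and did not pass in both readings, and Kdr and Nkx2-5 had direct ratios of -0.14 and -0.23.

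Of 27 pluripotency genes measured, 5 were lower, 0 were higher and 22 were neither in Bra over Rex1. The median of the list was -0.39 on the direct array and -0.51 in the second reading, below all but 0.0% of 10000 random lists matched on intensity in both. Fbxo15 had ratios of -2.65 and -1.69, Tcl1 of -1.99 and -1.44, Tdh, which encodes threonine dehydrogenase, of -1.60 and -1.20, and Dppa2 of -1.43 and -2.29. The core pluripotency factor gene Pou5f1 had ratios of -0.05 and -0.13, and Nanog of 0.84 and -0.31, with its readings on opposite sides of 0. Outside the list, Pogz was lower at -2.51 and -2.25, Mageb16 at -2.24 and -2.39, Rex2 at -2.29 and -1.76, Jade1 at -1.85 and -1.62, and Spp1, which encodes osteopontin, at -1.68 and -1.77.

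The list of primitive streak and nascent mesoderm genes had a median of 0.31 and 0.28 in Bra over Rex1, at percentile 100 of random lists in both readings. Of its 26 measured members 3 were higher, 0 were lower and 23 were neither. The Wnt-responsive transcription factor gene Sp5 had log2 ratios of 2.73 and 2.44, and Rspo3, which encodes a Wnt signalling enhancer, had 2.35 and 1.31. Rex1 was not well above background for either, so no exact fold can be read from these ratios. Lhx1 had ratios of 0.91 and 0.89, while Fgf17 went against the list on the direct array at -0.94 and read 0.12 in the second. Cdh2, the gene of N-cadherin, was higher at 1.73 and 1.46. The endoderm genes Sox17, at 1.24 and 1.19, and Cer1, at 1.21 and 1.21, were also higher. Of the Wnt target list, with medians of 0.04 and 0.26, Axin2 was higher by at least 2.16-fold with Rex1 dim. Here and below, such a bound for a dim gene is an estimate and not a guaranteed minimum.

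Among the other genes ranked highest in Bra over Rex1 were Ptpro at 1.62 and 2.72, Aldh3a1 at 1.51 and 1.69, Soga3 at 1.43 and 1.30 and Mogs at 1.39 and 1.26. For Ptpro and Aldh3a1, as for Cer1, Rex1 was well above background on 2 of 3 arrays. Without background subtraction the direct ratio of Ptpro was -0.0286. The probes of Ptpro disagreed, with direct ratios from -0.67 to 1.62 over 4 probes, and those of Fgf8 ranged from 0.66 to 2.36 over 2. Erap1 and Alox15, dim in Rex1, were higher by at least 3.91-fold and at least 3.70-fold. In the opposite direction, Fcer1a, at -1.17 and -1.02, and Cst10, at -1.18 and -1.31, were lower and were not well above background in Bra. In all, 287 genes or transcripts were higher and 55 lower, of which 42 and 53 were well above background in both populations. For the remaining 245 higher genes Rex1 was dim, and 6.78% of odorant, vomeronasal and taste receptor genes dim in Rex1 passed the same rule against 6.93% of other genes dim in Rex1.

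The comparison of Flk1 with Rex1 asked the same of cardiac mesoderm. Lmo2 and the endothelial genes Sox18 and Egfl7 were higher in the Flk1 population, and 6 of 27 pluripotency genes were lower. Lmo2, a transcriptional cofactor gene of blood and endothelial progenitors, was higher at 1.59 and 1.56, a fold of 3.0 on the direct array. The sort marker Zfp42, counted among those 6, was lower at -1.76 and -1.18. The sort marker Kdr, the gene of Flk1, had ratios of 0.68 and 0.64 and did not pass, T had 0.81 and 0.46, and Nkx2-5 had -0.10 and -0.87.

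The endothelium list had medians of 0.34 and 0.25 in Flk1 over Rex1, at percentiles 100 and 99.7 of random lists, with 2 of 21 measured members higher, 0 lower and 19 neither. The transcription factor gene Sox18 was higher at 1.27 and 1.39 and Egfl7 at 1.07 and 1.34, and Icam2 had ratios of 0.91 and 1.37. Cldn5 went against the list at -0.32 and -0.37, and the 2 probes of Erg disagreed, with direct ratios of -0.39 and 0.74. Of 19 measured blood and hemangioblast genes 2 were higher, Lmo2 and Etv2, the latter at 1.13 and 1.32, but the list medians of 0.02 and 0.09 lay inside the random range. Fst, the gene of follistatin, was higher at 1.90 and 1.58, Ctla2a at 1.67 and 2.05, Gng11 at 1.61 and 1.65, Donson at 1.68 and 1.96 and Slc30a5 at 1.52 and 1.83. Rex1 was well above background on 2 of 3 arrays for Gng11 and Donson and on 1 of 3 for Slc30a5 and Icam2. Without background subtraction the direct ratios of Slc30a5 and of Cstb, a cystatin gene, were -0.0105 and -0.0290. With Rex1 dim, Inka1 was higher by at least 5.02-fold, and the neuropilin gene Nrp1, at 2.48 and 1.57, Cstb, at 1.78 and 1.31, and Unk, at 1.95 and 1.56, were higher without an exact fold.

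The pluripotency list had medians of -0.36 and -0.46 in Flk1 over Rex1, below all but 0.0% of random lists in both readings, with 6 members lower and 0 higher. Fbxo15 had ratios of -2.25 and -2.14, Tdh of -1.70 and -1.51 and Klf5 of -1.36 and -1.37. Mageb16 was lower at -2.04 and -2.51, Tspan8 at -2.13 and -1.96, Spp1 at -2.04 and -1.88 and Pogz at -1.82 and -2.21. The primitive streak list had medians of 0.21 and 0.20, at percentiles 100 and 99.9, and the mesenchyme and extracellular matrix list 0.13 and 0.14, at 98.5 and 98.6, with Cdh2 higher at 1.44 and 1.10. Bmp4, a cardiac and lateral mesoderm list member, was lower at -1.04 and -1.23. In all, 171 genes or transcripts were higher and 66 lower, of which 63 and 59 were well above background in both populations. For 108 of the higher genes Rex1 was dim, and there 7.0% of receptor genes passed against 5.31% of other genes. Bra over Rex1 and Flk1 over Rex1 shared 121 higher and 37 lower genes, where independent lists of those sizes would share 1.98 and 0.146 and simulated unchanged genes shared 0 and 0. Both comparisons used Rex1 and the array of Nkx2.5 with Rex1, and part of this overlap may come from them.

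The comparison of Nkx2.5 with Rex1 asked which genes differed between cardiac progenitors and undifferentiated cells. Of 24 cardiac sarcomere genes 8 were higher in the Nkx2.5 population, together with the globin genes Hbb-y and Hbb-b2 and 5 of 21 endoderm genes, and 9 of 26 pluripotency genes were lower. Myl7, the atrial regulatory myosin light chain gene, was higher at 2.67 and 2.39, and Tnnt2, the cardiac troponin T gene, at 2.46 and 2.51, with Rex1 well above background on 1 of 3 arrays for Myl7 and 2 of 3 for Tnnt2. Nkx2-5 itself had ratios of 0.53 and 0.91 and did not pass. The sort marker Zfp42, counted among those 9 pluripotency genes, was lower at -1.68 and -2.25, and T and Kdr had direct ratios of -0.08 and 0.12.

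The cardiac sarcomere list had a median of 0.77 in both readings of Nkx2.5 over Rex1, at percentile 100 in both, with 8 of 24 members higher, 0 lower and 16 neither. Myl4 was higher at 1.82 and 2.47. Of the cardiac myosin heavy chain genes, Myh7 had a direct ratio of 0.01, and the 2 probes of Myh6 disagreed, at -0.22 for the brighter and 2.81 for the other. Myoz2 went against the list at -0.46 and -0.55. Of 18 measured cardiac transcription factor genes 2 were higher, Isl1 at 1.06 and 1.45 and Hey2 by at least 2.06-fold with Rex1 dim, the latter turning to -0.112 on the direct array without background subtraction, and the list medians of 0.16 and -0.01 lay inside the random range. The smooth muscle gene Tagln was higher at 1.35 and 1.93.

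Some genes of other lineages were also higher in Nkx2.5 over Rex1. The embryonic beta globin gene Hbb-y was higher at 2.57 and 2.18, with Rex1 well above background on 1 of 3 arrays, and Hbb-b2 at 2.12 and 2.60. The blood list medians of 0.14 and 0.10 lay inside the random range, with 3 of 21 members higher. The endoderm list had medians of 0.25 and 0.29, at percentile 99.5 in both readings, with 5 of 21 members higher and 0 lower. Ttr, the transthyretin gene, was higher at 1.98 and 1.83, with Rex1 well above background on 2 of 3 arrays, and Afp, the alpha-fetoprotein gene, at 2.60 and 3.33 with Rex1 dim and no exact fold. The keratin genes Krt18, at 1.85 and 1.99, and Krt8, at 1.51 and 1.43, were higher as well. Of the stress genes that can respond to cell dissociation, Jun was higher at 2.0 and 2.66 and Atf3, with Rex1 dim and no exact fold, at 2.71 and 2.15. The dissociation stress list had medians of 0.27 and 0.24 at percentiles 99.7 and 97.1, with the second inside the random range. Mpped2 was higher at 2.03 and 2.95, with Rex1 well above background on 2 of 3 arrays, and, with Rex1 dim and no exact fold, Nrp1 was higher at 2.61 and 3.21 and the vomeronasal receptor gene Vmn1r23 at 3.37 and 2.75.

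The pluripotency list had medians of -0.73 and -0.72 in Nkx2.5 over Rex1, below all but 0.0% of random lists in both, with 9 of 26 members lower, 0 higher and 17 neither. Dppa2 was lower at -3.38 and -2.72, Fbxo15 at -2.49 and -3.02 and Gdf3 at -2.20 and -2.93. Pou5f1 had ratios of -0.37 and -0.32, and Tfcp2l1 went against the list at 0.40 and 0.10. Rex2 was lower at -3.0 and -3.47, Mageb16 at -2.95 and -2.63 and Pogz at -2.14 and -2.08. Zfp120, dim in Nkx2.5, was lower by at least 2.67-fold, with its 2 probes at -1.76 and 0.31. The cell cycle list had medians of -0.23 and -0.13, at percentiles 0.0 and 0.905, with Ccne1 lower at -1.15 and -1.03 and Mki67 against it at 0.83 and 0.89. In all, 602 genes or transcripts were higher and 174 lower, of which 211 and 156 were well above background in both populations. For 391 of the higher genes Rex1 was dim, and there 19.0% of receptor genes passed against 12.3% of other genes.

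**Figure D2:**
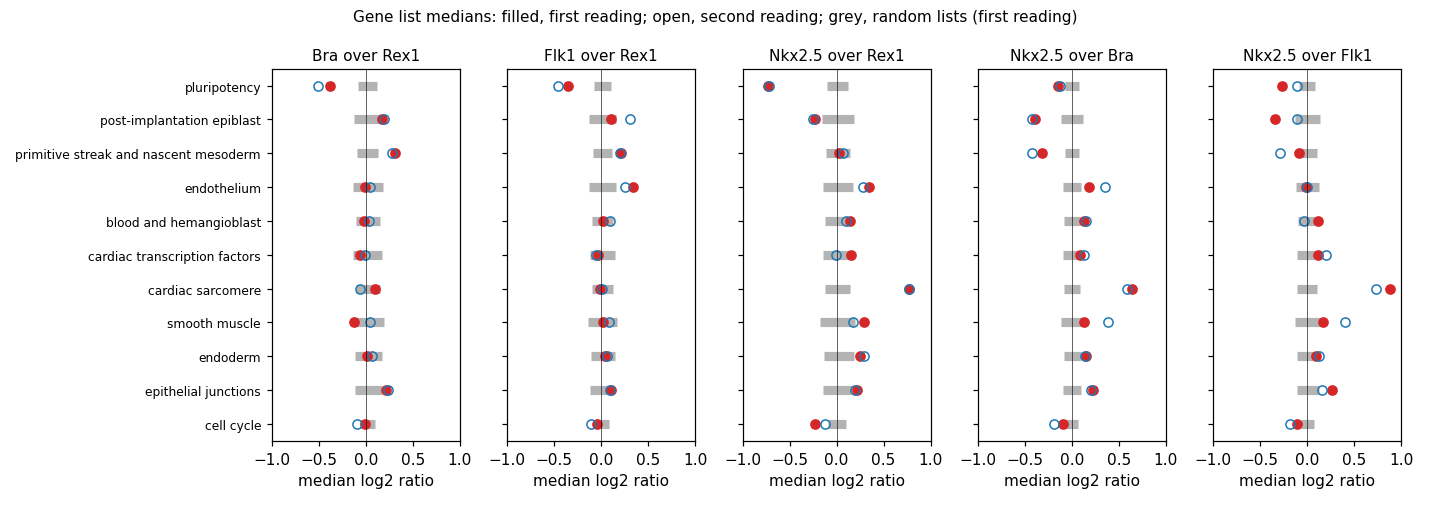
Median log2 ratio of 11 gene lists (x axis) in the 5 comparisons with an array of their own; filled points are the direct array, open points the second reading, and grey bars the central range of 10000 random lists matched on intensity. The cardiac sarcomere list reached 0.77 in Nkx2.5 over Rex1 and the pluripotency list -0.73.

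The comparison of Nkx2.5 with Bra asked what separated cardiac progenitors from early mesoderm. Of 24 sarcomere genes 5 were higher in Nkx2.5, as were 3 of 4 globin genes of the blood list and 3 of 22 endoderm genes, and 3 of 26 primitive streak genes were lower. Myl7 was higher at 2.75 and 2.42, a fold of 6.72, and Tnnt2 at 2.59 and 2.34, a fold of 6.04. Nanog was lower at -1.44 and -2.60. Nkx2-5 had ratios of 0.75 and 0.76, T of -0.81 and -1.16, Kdr of 0.11 and 0.26 and Zfp42 of -0.50 and 0.06, and none of these passed.

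The cardiac sarcomere list had medians of 0.64 and 0.58 in Nkx2.5 over Bra, at percentile 100 in both, with 5 of 24 members higher and 0 lower. Tnnc1 was higher at 1.39 and 1.60 and Csrp3 at 1.21 and 1.11. The smooth muscle list had medians of 0.13 and 0.38, at percentiles 98.7 and 100, with Acta2 higher at 1.58 and 1.17, while Mylk went against it at -0.14 and -1.08. Hbb-y was higher at 2.69 and 3.04, with Bra well above background on 1 of 2 arrays, and the blood list medians were 0.13 and 0.15, at percentiles 99.8 and 99.6. Spink1, a pancreatic secretory inhibitor gene listed with endoderm, was higher at 2.15 and 2.61, and the endoderm list medians were 0.15 and 0.13, at percentiles 99.8 and 97.9. Vmn1r23 was higher at 2.59 and 2.85 and Atf3 at 1.62 and 2.43, and the dissociation stress list had medians of 0.27 and 0.23. The endothelium list had medians of 0.18 and 0.35, at percentile 100 in both, with 0 members past the rule, and the epithelial junction list 0.22 and 0.20, at percentiles 100 and 99.9.

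The primitive streak list had medians of -0.32 and -0.43 in Nkx2.5 over Bra, below all but 0.0% of random lists in both, with 3 of 26 members lower. Fgf8 was lower at -1.16 and -1.81, Mixl1 at -1.08 and -1.50 and Sp5 at -1.07 and -1.35. The post-implantation epiblast list had medians of -0.39 and -0.43, with 1 of 13 members lower, Otx2 at -1.21 and -1.15 with its other probe at -0.39, and Cldn6 against the list at 0.75 and 0.84. Irf1 was lower at -1.44 and -1.59, Fst at -1.15 and -1.93 and Henmt1 at -1.15 and -1.66. The cell cycle list had medians of -0.09 and -0.19, at percentiles 0.35 and 0.0. In all, 68 genes or transcripts were higher and 15 lower, of which 63 and 15 were well above background in both populations. A limma loop fit over the 5 arrays, which compares hybridisations and not samples, gave 0 genes past its adjusted p threshold of 0.05. Of 23005 genes tested, 2166 had an unadjusted p under 0.05 in that fit.

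The comparison of Nkx2.5 with Flk1 asked what separated cardiac progenitors from cardiac mesoderm. Of 24 sarcomere genes 9 were higher in Nkx2.5, and Fst and the endothelial gene Sox18 were lower. Tnnt2 was higher at 2.29 and 2.44, a fold of 4.89. Nkx2-5 had ratios of 1.40 and 0.63 and did not pass, and Kdr had -0.52 and -0.56, T -0.54 and -0.90 and Zfp42 -0.50 and 0.07.

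The cardiac sarcomere list had medians of 0.88 and 0.73 in Nkx2.5 over Flk1, at percentile 100 in both, with 9 of 24 members higher and 0 lower. Myl7 was higher at 1.76 and 2.64. Acta2 was higher at 1.23 and 1.31, in a smooth muscle list with medians of 0.17 and 0.40 at percentiles 98.9 and 100. The cardiac and lateral mesoderm list had medians of 0.15 and 0.14, at percentiles 99.3 and 98.7, with 0 members past the rule. The 2 probes of its member Tbx1, of which only the brighter was counted, disagreed, with direct ratios of -0.06 and 2.04. Of the endothelial genes Sox18 was lower at -1.19 and -1.07 and Cldn5 higher at 1.36 and 1.31, and the list medians of -0.02 and -0.00 lay inside the random range. St3gal6 was higher at 2.05 and 2.16, S100g, a calcium-binding protein gene, at 2.04 and 2.01, Vmn1r23 at 2.04 and 3.01 and Hbb-y, with Flk1 well above background on 1 of 2 arrays, at 1.85 and 2.26. The blood list had medians of 0.11 and -0.04, with the second inside the random range at percentile 31.2, and 1 of 21 members was higher. Dppa2 was lower at -1.82 and -2.26, Rex2 at -1.92 and -1.52, Fst at -1.62 and -1.93, Enpp3 at -1.36 and -1.75, Crym at -1.35 and -1.28 and Reg1 at -1.29 and -1.38. The 2 probes of St3gal6 read 0.47 and 2.05 and those of Enpp3 -1.36 and -0.10.

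With Flk1 dim, Oxnad1 was higher by at least 1.67-fold and the odorant receptor gene Olfr273, without an exact fold, at 1.79 and 1.04. The direct ratio of Oxnad1 was -0.0185 without background subtraction. In all, 74 genes or transcripts were higher and 21 lower in Nkx2.5 over Flk1, of which 65 and 20 were well above background in both populations. The limma loop fit gave 0 genes past the adjusted threshold and 3205 of 23738 genes tested at an unadjusted p under 0.05. The comparisons of Nkx2.5 with Bra and with Flk1 shared 38 higher and 7 lower genes, where independent lists would share 0.203 and 0.0127 and simulated unchanged genes shared 0 and 0. Both used Nkx2.5 RNA, and both second readings used the array of Nkx2.5 with Rex1. Part of the overlap may come from these.

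The populations of day 4.5 shared no array, so Flk1 over Bra was read from differences between arrays. Of the endothelium list, Sox18 was higher in Flk1 at 2.19 and 1.56, with Bra well above background on 1 of 2 arrays, and the medians of the list were 0.21 and 0.14, at percentile 99.9 in both. Ctla2a was higher at 2.09 and 1.90, Gng11 at 1.58 and 1.45, H4c9 at 1.33 and 1.30 and Dusp2 at 1.62 and 1.12. Kdr had ratios of 0.83 and 0.63, T of -0.26 and -0.27, Zfp42 of -0.01 and 0.01 and Nkx2-5 of 0.13 and -0.65.

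In all, 5 genes were higher in Flk1 over Bra and 1 lower, Lrrc2 at -1.62 and -1.52 with Flk1 well above background on 1 of 2 arrays. The simulation gave 13 and 18 calls among unchanged genes, more than were observed. Its errors came from the triangle gaps, which hold dye effects that cancel in both readings of this comparison. The simulated errors may therefore be too large here, and the simulation cannot show whether these calls exceed error. The limma loop fit gave 0 genes past the adjusted threshold and 763 of 22613 genes tested at an unadjusted p under 0.05. Across genes well above background in both populations the readings correlated at r = 0.0863. The other comparisons gave 0.481 and 0.424 for Bra and Flk1 over Rex1, 0.735 for Nkx2.5 over Rex1, and 0.325 and 0.273 for Nkx2.5 over Bra and Flk1. A dye bias of a gene cancels in both readings of Flk1 over Bra. It enters both readings of Nkx2.5 over Rex1 in the same direction and can raise their correlation. These values are therefore not on equal terms, and genes are not independent replicates.

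Some list results depended on the processing. Of the 33 list medians outside the range of random lists in both readings, 31 shrank by over 1.5 times on the direct array without background subtraction, and 0 of the direct medians changed sign under that or 3 other alternatives. In the deposited table the direct median of the primitive streak list was 0.16 in Bra over Rex1. It was 0.18 for endothelium and 0.04 for mesenchyme and extracellular matrix in Flk1 over Rex1, and 0.13 for endoderm in Nkx2.5 over Rex1. In Nkx2.5 over Bra it was -0.26 for post-implantation epiblast, -0.03 for cell cycle and 0.09 for smooth muscle, and in Nkx2.5 over Flk1 0.06 for smooth muscle. With the mean of all probes the smooth muscle medians were 0.22 and 0.28 in those comparisons, and the endothelium median was 0.41 in Flk1 over Bra. The mesenchyme and extracellular matrix list in Flk1 over Rex1 no longer stood apart under any of the 4, with percentiles of 96.6 and 94.0 under median centring. The endoderm list in Nkx2.5 over Bra no longer did under median centring, at 94.6 in the second reading. The smooth muscle list lay inside the random range at 96.6 in the deposited table in Nkx2.5 over Bra, and at 96.0 without background subtraction in Nkx2.5 over Flk1. The cardiac and lateral mesoderm list did so in Nkx2.5 over Flk1, in the second reading, at 67.6 without background subtraction and 88.3 with the mean of all probes.

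The BMP and Nodal pathway list stood above random lists in both readings of Nkx2.5 over Rex1, with medians of 0.18 and 0.20 at percentiles 99.1 and 98.3, although 0 of 16 members were higher and 1 was lower. It no longer stood apart under any of the 4 alternatives. Its direct median was 0.10 with the mean of all probes and 0.02 without background subtraction, and its second turned to -0.02 without background subtraction and -0.01 in the deposited table. The following lists stood apart from random lists in both readings of no comparison. In Nkx2.5 over Rex1 their direct medians were 0.02 for the sort markers, 0.01 for paraxial mesoderm and somite, 0.10 for cardiac calcium handling, ion channels and peptides, -0.07 for cardiac energy metabolism, 0.07 for epicardium, -0.04 for neural ectoderm, 0.16 for fibroblast feeder markers, -0.02 for anterior Hox, -0.05 for posterior Hox, 0.17 for Wnt targets, 0.10 for the Notch pathway, 0.15 for cell cycle inhibitors, -0.03 for primordial germ cells and 0.08 for housekeeping genes. Among housekeeping genes B2m was higher in Nkx2.5 over Rex1, at 1.65 and 1.49, with direct ratios of its 3 probes from 0.63 to 1.65.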

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

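Leaving out spots marked Bad and requiring a bound of 2-fold for dim genes were the alternatives added after seeing the data. Counts below are higher and lower calls in the order Bra, Flk1 and Nkx2.5 over Rex1, Nkx2.5 over Bra, Nkx2.5 over Flk1 and Flk1 over Bra, and the counts of the fixed rule were 287 and 55, 171 and 66, 602 and 174, 68 and 15, 74 and 21, and 5 and 1. All 12 counts stayed within 1.5 times of these under median centring, with the mean of all probes and with no filter on dim probes. Of the 33 list medians outside the random range in both readings, 1, 31, 13 and 6 moved by over 1.5 times on the direct array, and 4, 7, 5 and 4 lists no longer stood apart, under median centring, without background subtraction, in the deposited table and with the mean of all probes, while 0 direct medians changed sign.

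Signal over background limits the calls. Without background subtraction the counts were 0 and 0, 0 and 0, 2 and 3, 3 and 0, 3 and 0, and 0 and 0, the closure SDs 0.102 and 0.107, and 13 of 84 named calls kept a log2 ratio of 1. There the direct ratios turned to -0.0286 for Ptpro in Bra over Rex1, -0.0105 for Slc30a5 and -0.0290 for Cstb in Flk1 over Rex1, -0.112 for Hey2 in Nkx2.5 over Rex1, and -0.0185 for Oxnad1 in Nkx2.5 over Flk1; the cause of these turns was not tested. An unsubtracted background shrinks the spread of ratios between genes by construction. It was not equal in the channels, with medians of 8154 in Cy3 and 3538 in Cy5 on the array of Bra and Rex1.

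In the deposited table the higher and lower calls were 103 and 39, 66 and 46, 285 and 160, 42 and 8, 37 and 18, and 4 and 2. With the scanner ratio they were 101 and 28, 68 and 37, 219 and 123, 42 and 9, 40 and 14, and 3 and 3. The cause was not tested. Requiring both populations well above background gave 42, 63 and 211 higher calls over Rex1 and 0 lower calls for Flk1 over Bra. The 2-fold bound gave 114, 94 and 341 and likewise 0, and leaving out Bad spots gave 174 and 379 higher calls for Bra and Nkx2.5 over Rex1; these settings remove dim genes by construction.

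The direct array alone gave 728 and 132 for Bra over Rex1, 771 and 181 for Flk1 over Rex1, 380 lower for Nkx2.5 over Rex1, 32 lower for Nkx2.5 over Bra, 289 and 53 for Nkx2.5 over Flk1, and 142 and 181 for Flk1 over Bra. The second reading alone gave 479 and 186, 349 and 202, 1242 and 335, 285 and 278, 298 and 274, and 10 and 49, and placed 50 list medians outside the random range against 33 in both readings. A rule on 1 reading is looser by construction. A fold of 4 gave 10 and 3, 4 and 5, 60 and 11, 9 and 0, 7 and 0, and 0 and 0.

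The dye term gave 179 lower for Bra over Rex1, 409 and 207, 1400 and 1095, 211 and 207, 252 and 203, and 13 and 7. The limma loop fit required a 2-fold estimate and adjusted p under 0.05. It gave 105 and 37 for Bra over Rex1, 40 and 16 for Flk1 over Rex1, and 840 and 268 for Nkx2.5 over Rex1. The others each gave 0 and 0, and there 0 genes passed the adjusted threshold at any size, against 154, 56 and 3569 over Rex1. Of 23005, 23738 and 22613 genes tested in those others, 2166, 3205 and 763 had an unadjusted p under 0.05 in that fit. Beyond the looser rule of the dye term, causes of the shifts in these counts were not tested. No paired analysis was possible because each pair of populations was hybridised once and the labels share no replicate numbers.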

Other observations

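The lists and their comparison with random lists were fixed before the data were examined, and the tests on receptor, globin and endoderm genes were chosen after the results they bear on were seen. The margins within which those values were held not to decide were also set after the values were known.

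Other lists stood apart from random lists in both readings. The epithelial junction list had medians of 0.22 and 0.24 in Bra over Rex1, with 0 of 17 members past the rule, and 0.27 and 0.16 in Nkx2.5 over Flk1, with 1 higher. In the deposited table neither stood apart, with direct medians of 0.03 and 0.10, and the first did not without background subtraction, at percentile 68.7 in the second reading. The endothelium list had medians of 0.34 and 0.29 in Nkx2.5 over Rex1, with 0 of 22 members past the rule, and the mesenchyme and extracellular matrix list 0.17 and 0.35, with 2 higher and a direct median of 0.47 with the mean of all probes. The endothelium median was 0.21 in the deposited table. The post-implantation epiblast list had medians of -0.23 and -0.25 in Nkx2.5 over Rex1, with 1 of 13 members higher and 0 lower, and did not stand apart with the mean of all probes, at -0.13 and -0.04, or without background subtraction, at -0.04 in both readings. The pluripotency list had medians of -0.14 and -0.13 in Nkx2.5 over Bra, with 2 of 27 members lower, and the second reading lay inside the random range under median centring, at percentile 5.79, and without background subtraction, at 9.98. In Nkx2.5 over Flk1 the cell cycle list had medians of -0.11 and -0.18 and the dissociation stress list 0.21 and 0.34, with direct medians of -0.28 and 0.12 in the deposited table, and -0.18 for the cell cycle list under median centring.

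Most genes higher than in Rex1 had Rex1 near background. Over the comparisons of Bra, Flk1 and Nkx2.5 with Rex1, odorant, vomeronasal and taste receptor genes were dim in Rex1 and bright in the other population in 419 cases, counting a gene once per comparison, and 46 of these passed the size rule, or 11.0%. The same held for 698 of 8229 cases of other genes, or 8.48%, and the ratio of these rates was 1.29, with a standard error of 0.186 that takes cases as independent although the comparisons share Rex1. Receptor genes of this kind are not known to act in these cells. The dim Cy3 signal of Rex1 on a high background may therefore account for part of the excess of higher over lower calls against Rex1. An excess also occurred between other populations, among genes well above background in both. It was 63 higher and 15 lower in Nkx2.5 over Bra, and 65 and 20 in Nkx2.5 over Flk1. Against Rex1 these counts were 42 and 53 for Bra, 63 and 59 for Flk1, and 211 and 156 for Nkx2.5. The second readings of Nkx2.5 over Bra and over Flk1 come from the arrays with Rex1. On their direct arrays Bra and Flk1 lay in Cy3, which again had the higher background. These counts therefore do not set the Rex1 arrays or the Cy3 background aside. Vmn1r23 was higher in Nkx2.5 over both Bra and Flk1, so such receptor genes may not all be silent here. Rex1 lay in Cy3 on each of its arrays, so genes silent in undifferentiated cells stay open as an untested biological explanation for individual genes.

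Of 4 globin genes of the blood list 3 were higher in the Nkx2.5 population than in Bra. The smaller readings of Hbb-bh1, Hbb-y, Hba-x and Hba-a1 ran from 0.84 to 2.69 with a median of 1.13. Blood cells among the sorted cells may be the source, but the globins are the pattern itself, and the median passes the value of 1 set for it by less than its SD of 0.464 over resampled genes. Blood cells and globin transcripts in Nkx2.5-positive cells therefore cannot be told apart here, and the isolation for Nkx2.5 would be meant to remove such cells.

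Endoderm products were uneven. Over Afp, Ttr, Apoa1, Apoa2, Apob, Apoa4, Trf and Rbp4 the smaller reading of Nkx2.5 over Bra ran from -0.12 to 1.74 with a median of 0.22, and 2 of the 8 passed. Endoderm cells among the sorted cells would bring these abundant transcripts together. Taken without a margin, the median lies under the bound of 0.25 set against such cells, but by less than its SD of 0.343 over resampled genes, so a contribution from such cells cannot be told apart from expression in the sorted cells.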
